A study of Brassica napus and Brassica napus
Plenodomus lingam with 36 samples.

How the data were processed

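RNA was sequenced from cotyledons of 36 samples as polyA libraries, per the labels. The labels give genotype, day, inoculation and replicate number, call the replicates biological, and were the only source of the grouping. The authors deposited a table of FPKM, in which fragments are scaled by transcript length and by the number of mapped fragments, for 100836 gene models and each library, of which 100446 carry Brassica napus gene names and 390 were assembled by the authors' software. The submitters' processing notes name Trimmomatic, TopHat2, Cufflinks 2.2.1, bedtools, Cuffnorm and Cuffdiff, without order or role. The genome build is not given in the sources used here, so positions are those of the deposited table. A further deposited table holds other values, the counts of genes that the authors called per genotype and day, which are printed as theirs only. No sample column was left unassigned (0 columns). How reads that match several copies were shared is not stated, so single copies of a gene are uncertain.

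FPKM values are not counts, so no count model was used. Low values in a library fell on steps that depend on gene length, with fragments of 200 ± 80 bp assumed. The step was found on genes of 1000 to 4000 bp and checked on a partly overlapping range of shorter genes. Of their low values, between 79.6% and 99.1% lay within 0.1 of a whole number of fragments, against 20% by chance. The recovered fragment totals give the depth of each library, and 3 fragments were taken as the floor. No pair of replicates differed by less than sampling noise, over genes with at least 20 fragments (lowest chi-square per degree of freedom 1.19). This argues against a library entered more than once, but cannot show that replicates came from separate plants. They are counted separately because the labels call them biological.

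Genes with at least 1 FPKM in at least 2 libraries (58564) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), which understates the change of low genes. A model with a mean per group was fitted to all 36 libraries, with the moderated variance following the mean (eBayes with trend), two-sided p-values and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes in the text come from this fit, unless a left-out library or another fit is named beside them. The comparisons were infected against mock tissue on each day in each genotype, the difference of these responses between genotypes, DF78 against Westar at 0 dpi, and mock tissue of 11 dpi against 0 dpi in each genotype. These comparisons, their test, the 17 gene lists and the rule for named genes were fixed before the data were examined, while some of the alternatives and of the tests of possible artifacts were chosen afterwards.

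Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 17 lists of a comparison. The lists hold 279 Arabidopsis genes, of which 203 were matched through the deposited annotation text to 1083 Brassica napus genes. The pattern receptor list also holds early signalling genes, among them kinases, oxidases and WRKY factors. Over the 12 comparisons the preset test called 114 list results, of which 38 also passed with an estimated correlation. Named genes are, for each comparison, from the 10 largest rises and 10 largest falls among called genes whose libraries do not overlap between groups and with a highest group mean of at least 5 FPKM (no overlap condition for differences between genotypes), up to 4 called members of each list, and a panel of 35 genes, each represented by the copy with the highest mean FPKM. By chance, libraries of 3 and 2 samples do not overlap in 20% of genes and those of 3 and 3 samples in 10%. Of the panel 28 genes matched a copy and 27 were tested. The deposited annotation gives no match for 14968 gene models.

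The fits were tested on simulated data drawn at the real depths with 200 genes changed by known folds of 2, 4 and 8. These genes were drawn from those with a mean of at least 5 FPKM, with a dispersion of 0.1 in every group. Recovery in lower genes or in groups with outlying replicates was not tested. As designed, the test recovered 1.5%, 42.4% and 80.3% of the changed genes in DF78 at 3 dpi (55952 genes). In Westar at 3 dpi it recovered 0%, 25.8% and 75.8% (55976), and in DF78 at 11 dpi 1.5%, 18.2% and 72.7% (55872). For the difference between genotypes it recovered 0%, 3% and 39.4% at 3 dpi (56006) and 0%, 3% and 18.2% at 11 dpi (55923). Alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios rescaling, quantile normalization, a fit to only the groups compared, the replicate number as a block, no trend with robust variances, an absolute log2 change of at least 1, the 0 dpi libraries as control and leaving out each library in turn. Alternatives chosen after seeing the data were voom weights on the recovered fragments, array weights and leaving out the 3 shallow libraries. The Westar mocks of 3 and 11 dpi as control at 7 dpi were also chosen then. The voom fit changes the scale as well as the weights, to log2 of fragments plus a small constant per library size. On that scale a gene at 0 takes a higher value in a shallower library. Where leaving out a mock leaves a single library in its group, that library is assumed to vary like the other groups. Correlations and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Annotated plant families with at least 20 genes (313) were tested like the lists.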

Results

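Gene expression was measured in cotyledons of oilseed rape (Brassica napus), an allotetraploid whose genome joins an A and a C subgenome, after inoculation with Leptosphaeria maculans, the fungus that causes blackleg. Per the labels, DF78 is a resistant breeding line carrying the resistance genes Rlm3 and LepR1, and Westar is a susceptible cultivar. Seedlings aged 7 days received 10 µL of isolate D3 or of water (mock) on the cotyledons, and tissue was sampled on day 0 and on days 3, 7 and 11 after inoculation (dpi). The 36 libraries fell into 14 groups, with 3 biological replicates per group of 0 dpi and of infected tissue and 2 per mock group of 3, 7 and 11 dpi. The comparisons ask how each genotype responded to the fungus on each day and whether the responses differed between the genotypes. Levels are given as mean FPKM ± SD with n = 3 for infected and 0 dpi groups and n = 2 for mock groups, and changes as differences of log2(FPKM + 1) with their standard error. Near-identical copies of a gene on the A and C subgenomes share reads, so the level of a single copy is uncertain. Fungal transcripts were not analysed here.

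Depth was recovered from the steps of low FPKM values and ran from 0.337 to 19.9 M fragments per library, with a median of 5.85 M. The 3 libraries under 1 M fragments all belonged to Westar at 7 dpi, namely mock replicate 1 (0.34 M), mock replicate 2 (0.563 M) and infected replicate 3 (0.337 M), and every other library held at least 1.38 M. In those mocks, 3 fragments on a gene of 1 kb correspond to 5.81 and 3.63 FPKM, so a gene listed at 0 there can be expressed at several FPKM. The first principal component held 36.6% of the variance over all genes tested and the second 13%. Replicate 2 of infected DF78 at 7 dpi lay at 105.9 and 3.56 on these components, while the other two replicates lay at 38.4 and -107, and at 36.4 and -102. Replicate 1 of Westar at 0 dpi lay at 20.6 on the second component against 103.5 and 105.6 for the other two. The Westar mocks of 7 dpi lay at -71.7 and -85.1 on that component, and all other Westar libraries at -10.1 or above.

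**Figure D1:**
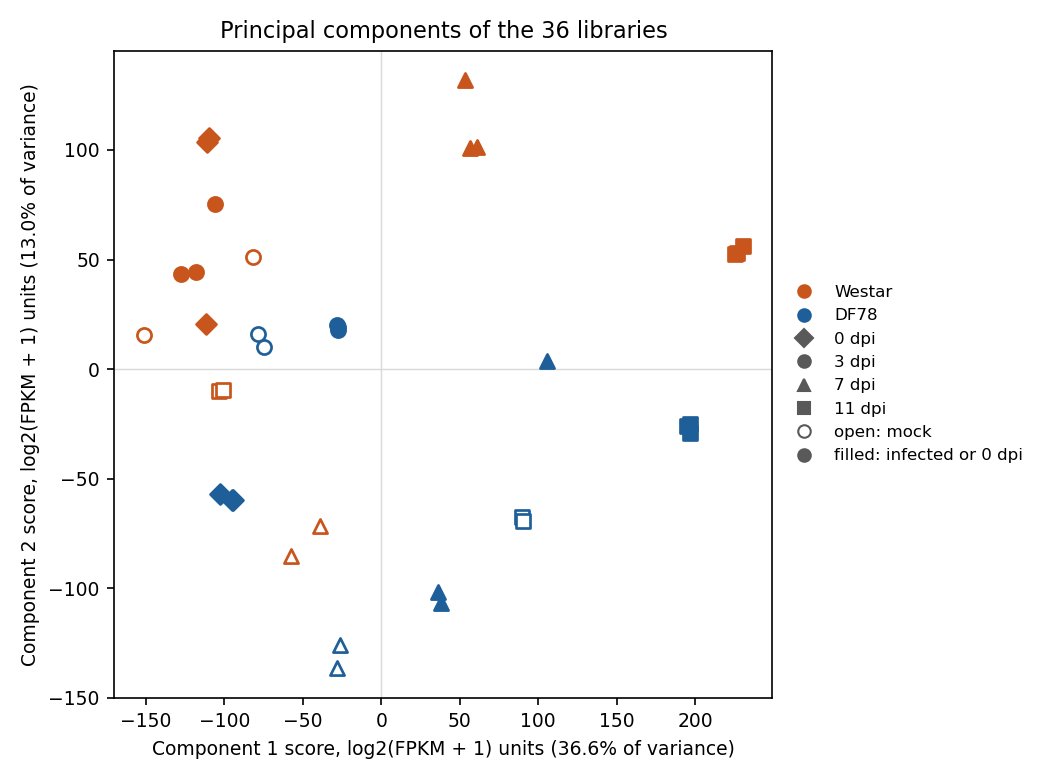
Scores of the 36 libraries on the first (x axis, 36.6% of the variance) and second (y axis, 13%) principal components of log2(FPKM + 1), both without unit, with orange for Westar, blue for DF78, diamonds for 0, circles for 3, triangles for 7 and squares for 11 dpi, open symbols for mock and filled symbols for infected or 0 dpi libraries. Infected libraries of 11 dpi sit between 195 and 230.3 on the first component, and replicate 2 of infected DF78 at 7 dpi sits at 105.9, apart from the other two of its group at 36.4 and 38.4.

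In the 0 dpi libraries, which the labels call mock, some genes high in DF78 were near silent in Westar. A chitinase family gene (BnaA10g05680D, chromosome A10, 3646850 to 3650151) stood at 699.8 ± 35.4 against 0.247 ± 0.263 FPKM in DF78 and Westar (log2 change 9.15, SE 0.23, adjusted p = 3.2e-20). Glycine-rich protein 3 (BnaA09g54870D, chromosome A09_random, 2841360 to 2843640) stood at 1305 ± 90.9 against 1.49 ± 0.537 FPKM (log2 change 9.05, SE 0.20, adjusted p = 7.3e-21). A gene of the pollen coat protein family that binds an S locus-related glycoprotein (BnaAnng02700D) and metallothionein 2B (BnaC03g00710D), a metal-binding protein, were also higher in DF78, by 6.64 (SE 0.62) and 6.13 (SE 1.02). An S-adenosylmethionine decarboxylase gene of polyamine synthesis (BnaA03g27900D) was lower in DF78, at 4.82 ± 3.42 against 223 ± 21.1 FPKM. In all, 11642 of the 58564 genes tested differed, 5945 higher and 5697 lower in DF78.

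Defence and phenylpropanoid genes were among those higher in DF78 at 0 dpi. The first enzyme of phenylpropanoid synthesis, PAL1 (BnaA04g21230D), stood at 98.4 ± 11.2 against 17.6 ± 12.03 FPKM (log2 change 2.60, SE 0.33, adjusted p = 3.2e-06). PR1 (BnaC03g45470D), a marker of salicylic acid signalling, was higher by 2.65 (SE 0.48). CYP79B2 (BnaC07g51280D), which in Arabidopsis acts in indole glucosinolate and camalexin synthesis, was higher by 2.82 (SE 0.40). The defence regulator WRKY33 (BnaC03g21360D) was higher by 2.11 (SE 0.36) and the sulfate-assimilation gene APR2 (BnaA03g59800D) by 3.52 (SE 0.24). The preset test called 9 of the 17 lists, and none of these calls held with an estimated correlation. Within the phenylpropanoid list 24 of 59 were higher and 2 were lower (28 and 3 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.096). Among camalexin and indole glucosinolate genes 21 of 53 were higher (21 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.30). For the sulfur list 13 of 49 were higher and 1 was lower (18 and 3 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.30). Among the salicylic acid genes 17 of 63 were higher (18 up and 1 down adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.42). For photosynthesis 18 of 162 were higher and 53 were lower (21 and 63 adjusted over the list alone), with adjusted p = 0.52 with an estimated correlation, and the preset call was also lost after quantile normalization. No call was made for CYP79B2 and WRKY33 in a fit to only the groups compared. Replicate 1 of Westar at 0 dpi stood apart from the other two, and without it the count of genes rose to 15665. The count was 6102 without Westar replicate 2 and 5958 without Westar replicate 3.

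In mock-inoculated Westar cotyledons, vegetative storage protein 2 (VSP2, BnaC02g41060D, chromosome C02, 44052897 to 44054260), a jasmonate-responsive protein, rose between 0 and 11 dpi from 9.62 ± 5.33 to 2959.8 ± 29.7 FPKM (log2 change 8.23, SE 0.60, adjusted p = 7.2e-10). The jasmonate synthesis genes LOX2 (BnaA07g19600D) and AOS (BnaA02g23180D) rose by 2.95 (SE 0.29) and 4.01 (SE 0.35), a Kunitz trypsin inhibitor (BnaA07g30760D) by 7.38 (SE 0.64) and epithiospecifier protein (BnaA06g01390D), which directs glucosinolate breakdown, by 7.12 (SE 0.70). The aquaporin delta-TIP (BnaA03g34110D) fell from 317 ± 117 to 1.96 ± 0.382 FPKM. Of the 58564 genes tested, 6000 rose and 5553 fell (11553 in all). CYP79B3 (BnaA04g12790D) rose by 5.27 (SE 0.43) and basic chitinase CHIB (BnaA03g32280D) by 5.53 (SE 0.63). The preset test called 10 lists and none held with an estimated correlation. Within the camalexin and indole glucosinolate list 21 of 53 rose (22 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.094). Among aliphatic glucosinolate genes 14 of 25 rose and 1 fell (14 and 1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.094). For the jasmonate list 11 of 48 rose and 1 fell (12 and 1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.19). Among the photosynthesis genes 1 of 162 rose and 98 fell (2 and 119 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.13). No call was made for CHIB and LOX2 in a fit to only the groups compared. The count was 7343 without Westar 0 dpi replicate 2, 7315 without replicate 3, 4973 without mock replicate 1 and 6096 without mock replicate 2.

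In mock-inoculated DF78 photosynthesis genes fell and detoxification genes rose over the same interval. NAP (BnaC06g30680D), a transcription factor of leaf senescence, rose from 0.16 ± 0.277 to 49.4 ± 3.53 FPKM (log2 change 5.46, SE 0.45, adjusted p = 5.6e-10), and the chlorophyll breakdown gene PPH (BnaA02g01880D) by 4.57 (SE 0.33). Glutathione transferase GSTU24 (BnaC08g37940D, chromosome C08, 34484992 to 34486028) rose from 0.16 ± 0.142 to 158 ± 5.83 FPKM. The light-harvesting gene LHCB1.3 (BnaC07g09400D) fell from 875 ± 79.7 to 20.8 ± 2.47 FPKM (log2 change -5.33, SE 0.27, adjusted p = 8.1e-14), as did the Rubisco small subunit RBCS1B (BnaCnng55860D) and carbonic anhydrase 1 (BnaCnng05580D), with log2 changes of -5.00 (SE 0.40) and -7.14 (SE 0.85). In the photosynthesis list 2 of 162 rose and 152 fell (2 and 154 adjusted over the list alone, adjusted p = 0.0045 with an estimated correlation). In the detoxification list 28 of 53 rose and 1 fell (29 and 1 adjusted over the list alone, adjusted p = 0.0036 with an estimated correlation). Within the senescence list 16 of 29 rose and 5 fell (17 and 5 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.052). Over all genes 9251 rose and 8701 fell (17952 of 58564). Without mock replicate 1 the count was 11234 and without mock replicate 2 it was 11406. Across genes, the changes of the mocks of the genotypes correlated with Pearson r = -0.0060 and Spearman rho = -0.0050, where genes are not independent replicates.

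At 3 dpi infected DF78 carried higher levels of salicylic acid and detoxification genes than its mock. PR1 (BnaC03g45470D, chromosome C03, 30460477 to 30461095) rose from 31.6 ± 4.37 to 531 ± 42.8 FPKM (log2 change 4.03, SE 0.53, adjusted p = 5.6e-05). Osmotin 34 (BnaC01g41460D, chromosome C01_random, 630001 to 631175), an antifungal thaumatin-type protein, rose from 8.8 ± 2.09 to 176 ± 16.5 FPKM (log2 change 4.18, SE 0.57, adjusted p = 8.5e-05). The secreted lipase GLIP3 (BnaA08g00970D, chromosome A08, 691965 to 693868) rose from 0.665 ± 0.827 to 37.6 ± 3.43 FPKM (log2 change 4.63, SE 0.53, adjusted p = 6.4e-06). The glucanase PR2 (BnaA04g02500D), the pipecolate synthesis gene ALD1 (BnaA03g38440D) and PR4 (BnaC03g33890D), a chitin-binding protein, rose by 3.46 (SE 0.54), 2.84 (SE 0.40) and 3.02 (SE 0.31). In all 363 of the 58564 genes tested changed, 322 up and 41 down. Voom weights gave 680 up and 43 down, while a fit to only the groups compared gave 581 and 377. Array weights gave 2439 up and 1597 down, and the 0 dpi libraries as control 4526 and 4693.

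In the salicylic acid list 18 of 63 rose (35 adjusted over the list alone, adjusted p = 0.00020 with an estimated correlation). Of the detoxification genes 10 of 53 rose (12 adjusted over the list alone, adjusted p = 3.4e-06 with an estimated correlation), led by the glutathione transferases GSTF2 (BnaA03g26140D, from 0.415 ± 0.0354 to 12.6 ± 0.823 FPKM) and GSTF3 (BnaC03g30870D, from 3.88 ± 0.0919 to 35.5 ± 0.739 FPKM). For chitinases, glucanases and defensins 5 of 28 rose (7 up and 1 down adjusted over the list alone, adjusted p = 0.018 with an estimated correlation). For aliphatic glucosinolates 3 of 25 rose (7 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation), among them MYB29 (BnaC03g03210D), a regulator of that pathway, by 1.13 (SE 0.14). Among pattern receptor and early signalling genes no member of 77 passed over all genes. There were 16 up and 0 down at an unadjusted p under 0.05, and 3 up and 0 down adjusted over the list alone. The list passed at adjusted p = 0.044 with an estimated correlation. Among ethylene genes 4 of 50 rose (7 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.066). For the senescence list 1 of 29 rose (1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.066). The senescence-associated dehydrogenase gene SAG13 (BnaA04g17120D) rose from 0.085 ± 0.1202 to 6.53 ± 1.63 FPKM. Among the endoplasmic reticulum folding genes no member of 25 passed over all genes, against 8 up and 0 down at an unadjusted p under 0.05 and 4 up and 0 down adjusted over the list alone, a call lost with an estimated correlation (adjusted p = 0.066). Within the camalexin and indole glucosinolate list 2 of 53 rose (2 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.078). Among sulfur genes 1 of 49 rose (1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.11). For the jasmonate list 1 of 48 rose (1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.42). Among the photosynthesis genes 1 of 162 fell (1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.18). The test no longer called MYB29 and PR4 in a fit to only the groups compared, nor GSTF3 with a pseudocount of 0.1. Without mock replicate 1 the count of genes fell to 194 and without mock replicate 2 to 123.

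Infected Westar differed from its mock in few genes at 3 dpi. PAP1 (BnaAnng41910D), a regulator of anthocyanin synthesis, fell from 7.58 ± 0.813 to 1.03 ± 0.356 FPKM (log2 change -2.09, SE 0.34, adjusted p = 0.0095), against a difference of 0.12 with the 0 dpi libraries as control. The light-harvesting gene LHCB4.1 (BnaC02g40680D) was listed at 0 in both mocks and averaged 5.76 FPKM in the infected libraries (adjusted p = 0.0069). No call was made for LHCB4.1 and PAP1 in a fit to only the groups compared, with voom weights and with array weights, nor for PAP1 with a pseudocount of 0.1. Further calls were lost for LHCB4.1 with the 0 dpi libraries as control. PR1 was measured at 55.4 ± 18 against 34.6 ± 36.6 FPKM (log2 change 1.14, SE 0.53, adjusted p = 0.53) and PR2 (BnaC04g24330D) at 188 ± 20.2 against 131 ± 45.8 FPKM (log2 change 0.55, SE 0.46, adjusted p = 0.83), and neither passed. In all 91 of the 58564 genes tested changed, 50 up and 41 down, against 5153 at an unadjusted p under 0.05. A fit to only the groups compared called 0 genes, array weights called 2, and the 0 dpi libraries as control gave 2267. After quantile normalization 44.4% of the called genes were up, against 54.9% as deposited, and with voom weights 17 rose and 47 fell. A pseudocount of 0.1 gave 78 up and 31 down. The preset test called 8 lists and none held with an estimated correlation. In the salicylic acid list no member of 63 passed over all genes, against 7 up and 1 down at an unadjusted p under 0.05 and 0 up and 0 down adjusted over the list alone, with adjusted p = 0.58 with an estimated correlation. In the phenylpropanoid list no member of 59 passed over all genes, against 0 up and 12 down at an unadjusted p under 0.05 and 0 up and 0 down adjusted over the list alone, with adjusted p = 0.14 with that estimate. The Westar mocks of 3 dpi lay apart on the first principal component, at -151 and -81.9. The PR1 level became a call without mock replicate 2 (0.036 adjusted p). The count was 472 without infected replicate 1, 144 without infected replicate 3 (113 up and 31 down), 2878 without mock replicate 1 and 181 without mock replicate 2.

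The response at 3 dpi differed between the genotypes in 103 of the 58564 genes tested, 81 with the higher change in DF78 and 22 in Westar. An oxygenase of the 2-oxoglutarate family (BnaC05g02450D) stood at 38 ± 4.26 FPKM in infected and 1.78 ± 0.948 FPKM in mock DF78 against 0.62 ± 0.108 and 1.31 ± 1.86 FPKM in Westar (difference 4.08, SE 0.62, adjusted p = 0.0023). A lipid-transfer-like gene (BnaC03g14230D) differed by 3.57 (SE 0.36) and SAG13 by 2.99 (SE 0.47), while a methyltransferase gene (BnaA10g25800D) differed by -2.26 (SE 0.38). Calls were lost for SAG13 and the oxygenase gene in a fit to only the groups compared and for the oxygenase gene with voom weights and with a pseudocount of 0.1. PR1 differed by 2.89 (SE 0.75) and did not pass (adjusted p = 0.17), although it did without Westar mock replicate 1 (adjusted p = 0.00103). Among salicylic acid genes 3 of 63 changed more upward in DF78 (17 adjusted over the list alone), with adjusted p = 0.026 with an estimated correlation. In the detoxification list 1 of 53 changed more upward in DF78 (8 adjusted over the list alone, adjusted p = 0.0044 with an estimated correlation). In the aliphatic glucosinolate list 2 of 25 changed more upward in DF78 (4 adjusted over the list alone, adjusted p = 0.026 with an estimated correlation). In the sulfur list 1 of 49 changed more upward in DF78 (5 adjusted over the list alone, adjusted p = 0.041 with an estimated correlation). For the chitinase list no member of 28 passed over all genes (7 above and 1 below at an unadjusted p under 0.05, 3 and 0 adjusted over the list alone), and its call was lost with adjusted p = 0.28 with an estimated correlation. The count was 157 without Westar infected replicate 3 (82 with the higher change in DF78 and 75 in Westar), 1862 without Westar mock replicate 1 (738 and 1124, so that the majority turned), 68 without DF78 infected replicate 3 and 34 without DF78 mock replicate 2.

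At 7 dpi salicylic acid, pattern receptor and early signalling genes stood higher in infected DF78 than in its mock. A thaumatin-like pathogenesis-related gene (BnaC05g14950D, chromosome C05, 8918905 to 8920293) rose from 1.07 ± 0.1697 to 442 ± 241 FPKM (log2 change 7.61, SE 0.76, adjusted p = 1.1e-07). A chitinase gene (BnaC04g53030D, chromosome C04_random, 680771 to 682319) rose from 2.69 ± 0.0919 to 275 ± 59.7 FPKM (log2 change 6.20, SE 0.72, adjusted p = 1.3e-06). PR1 rose from 39.1 ± 3.88 to 1495 ± 629 FPKM, GLIP3 by 6.33 (SE 0.53), osmotin 34 by 6.08 (SE 0.57), PR4 by 5.57 (SE 0.31) and ALD1 by 4.63 (SE 0.40). The lipid transfer protein gene LTP4 (BnaA02g07110D, from 22.6 ± 3.94 to 0.050 ± 0.0866 FPKM) fell, as did LTP3 (BnaC02g10060D, from 47.5 ± 10.6 to 1.69 ± 1.46 FPKM). In all 3677 of the 58564 genes tested changed, 2474 up and 1203 down (3517 and 2750 with voom weights).

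In the salicylic acid list 41 of 63 rose (45 adjusted over the list alone, adjusted p = 0.00098 with an estimated correlation). In the pattern receptor list 26 of 77 rose (37 up and 1 down adjusted over the list alone, adjusted p = 0.0040 with an estimated correlation), with WRKY33 (BnaC07g27590D) and the wall-associated kinase WAK1 (BnaCnng45090D) up by 2.58 (SE 0.25) and 1.89 (SE 0.20). Among chitinases, glucanases and defensins 10 of 28 rose (15 adjusted over the list alone, adjusted p = 0.0040 with an estimated correlation). Among detoxification genes 19 of 53 rose (19 adjusted over the list alone, adjusted p = 7.0e-05 with an estimated correlation). Among ethylene genes 14 of 50 rose (20 up and 1 down adjusted over the list alone, adjusted p = 0.037 with an estimated correlation). Protein folding genes of the endoplasmic reticulum moved with them, as 15 of 25 rose (19 adjusted over the list alone, adjusted p = 0.029 with an estimated correlation), and calreticulin CRT3 (BnaC08g43170D) rose from 11.8 ± 0.368 to 66.5 ± 25.6 FPKM. Within the camalexin and indole glucosinolate list 16 of 53 rose and 3 fell (29 and 6 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.089). Among photosynthesis genes 3 of 162 rose and 33 fell (3 and 62 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.12). For the phenylpropanoid list 3 of 59 rose and 3 fell (3 and 5 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.27). Among the senescence genes 3 of 29 rose and 1 fell (5 and 1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.064). CYP81F2 (BnaC02g11750D) of indole glucosinolate modification rose by 2.36 (SE 0.24) and RBCS1B (BnaC02g17150D) fell from 8.51 ± 1.54 to 0.267 ± 0.244 FPKM. The test no longer called ALD1, CRT3, CYP81F2, LTP3, osmotin 34, PR1, PR4, RBCS1B, WAK1 and WRKY33 in a fit to only the groups compared, nor LTP3 with the 0 dpi libraries as control. The fit to only the groups compared called 202 genes. Infected replicate 2 stood apart from the other two, and without it 2379 genes were called, against 1477 without mock replicate 1 and 1929 without mock replicate 2.

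Infected Westar at 7 dpi showed higher salicylic acid and detoxification genes than its mock. A chitinase family gene (BnaC09g51720D, chromosome C09_random, 948730 to 950079) rose from 1.37 ± 1.94 to 254 ± 6.22 FPKM (log2 change 7.04, SE 0.54, adjusted p = 3.9e-10). In these mocks 3 fragments on a gene of 1 kb give 5.81 and 3.63 FPKM. The size of a change from a lower mock mean, as here, is uncertain. The defensin PDF1.2a (BnaC02g23620D, chromosome C02, 20546782 to 20547438) rose from 15.1 ± 1.92 to 1959 ± 114 FPKM (log2 change 6.93, SE 0.79, adjusted p = 2.6e-07). PR1 rose from 57.3 ± 44.02 to 827 ± 103 FPKM (log2 change 4.06, SE 0.53, adjusted p = 2.0e-06), while VSP2 fell from 73.9 ± 28.4 to 1.24 ± 1.34 FPKM (log2 change -5.17, SE 0.60, adjusted p = 3.5e-07) and the aquaporin PIP2 (BnaA03g17030D) from 465 ± 14.1 to 3.47 ± 1.35 FPKM. The flavonoid gene DFR (BnaA09g15710D) and the inositol synthesis gene MIPS1 (BnaA01g34710D) fell, with log2 changes of -6.19 (SE 0.83) and -6.08 (SE 0.99). In all 22014 of the 58564 genes tested changed, 12174 up and 9840 down. Of 55818 unchanged genes simulated at the depths of this comparison 3213 were called, against 22 with voom weights on the recovered fragments, and on the real data that weighting called 5101 genes, 1610 up and 3491 down. The median change over all genes was 0.09, -0.05 with quantile normalization and -0.46 with voom weights, so changes are relative to these. The voom fit also raises genes near 0 in the shallow mocks, so its median and directions are not an effect of the weights alone.

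Of the salicylic acid genes 47 of 63 rose and 2 fell (48 and 2 adjusted over the list alone, adjusted p = 0.038 with an estimated correlation), among them WRKY70 (BnaA07g16850D, from 2.15 ± 0.332 to 70.9 ± 2.44 FPKM), PR2 (BnaA04g02490D) by 4.51 (SE 0.50) and ALD1 by 3.97 (SE 0.40). In the detoxification list 27 of 53 rose and 7 fell (28 and 8 adjusted over the list alone, adjusted p = 0.038 with an estimated correlation), with GSTF3 (BnaC03g30870D) up from 2.77 ± 3.92 to 90.9 ± 17.5 FPKM. With voom weights 14 detoxification genes rose and 2 fell, and the list's median change was 0.15 against 0.73, while 31 salicylic acid genes rose and 0 fell, with a median of 2.27 against 2.15. Within the jasmonate list 3 of 48 rose and 25 fell (3 and 26 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.13). Among endoplasmic reticulum folding genes 22 of 25 rose (22 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.13). Calnexin CNX1 (BnaA06g21300D) rose by 4.02 (SE 0.32), and LOX2 fell, with a log2 change of -1.78 (SE 0.29). For the phenylpropanoid list 7 of 59 rose and 24 fell (10 and 25 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.20). Among the aliphatic glucosinolate genes 3 of 25 rose and 11 fell (3 and 12 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.28). F5H1 (BnaC01g02400D) of lignin synthesis and CYP83A1 (BnaA04g06630D) of glucosinolate synthesis fell, with log2 changes of -2.38 (SE 0.32) and -3.72 (SE 0.49). For pattern receptors and early signalling 38 of 77 rose and 6 fell (40 and 6 adjusted over the list alone), with adjusted p = 0.13 with an estimated correlation. The calcium-dependent kinase CPK5 (BnaA01g02090D) of that list rose by 3.28 (SE 0.36). For ethylene 18 of 50 rose and 3 fell (18 and 3 adjusted over the list alone), with adjusted p = 0.48 with an estimated correlation, and the median change of that list turned from 0.44 to -0.11 with voom weights. For photosynthesis 62 of 162 rose and 14 fell (66 and 15 adjusted over the list alone), with adjusted p = 0.69 with an estimated correlation, and rubisco activase (BnaA05g05840D) fell from 621 ± 12.7 to 79.98 ± 7.13 FPKM. PR4 and SAG13 were listed at 0 in both mocks and averaged 15.4 and 31.8 FPKM in infected tissue. No call was made for ALD1 in a fit to only the groups compared, nor for PR4 with voom weights. Further calls were lost for CPK5, LOX2 and MIPS1 with the 0 dpi libraries as control. Voom weights gave 0 up and 16 down in the jasmonate list, 12 and 0 in protein folding, 1 and 9 in phenylpropanoids, 2 and 8 in aliphatic glucosinolates, 12 and 1 in pattern receptors, 6 and 0 in ethylene and 30 and 9 in photosynthesis. In these mocks GRP3 (BnaA09g54870D) and chitinase BnaA10g05680D, both high in DF78 at 0 dpi, stood at 301 ± 10.02 and 219 ± 13.3 FPKM, against at most 5.18 and 2.48 FPKM in any other Westar group.

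The responses at 7 dpi differed between the genotypes in 6131 of the 58564 genes tested, 2443 with the higher change in DF78 and 3688 in Westar. The thaumatin-like gene BnaC05g14950D stood at 442 ± 241 FPKM in infected and 1.07 ± 0.1697 FPKM in mock DF78 against 51.6 ± 21.5 and 44.2 ± 59.6 FPKM in Westar (difference 6.02, SE 1.07, adjusted p = 0.00079). VSP2 stood at 3.73 ± 2.75 and 7.29 ± 1.48 FPKM in DF78 against 1.24 ± 1.34 and 73.9 ± 28.4 FPKM in Westar (difference 4.11, SE 0.85, adjusted p = 0.0028), and a second LOX2 copy (BnaA07g24880D) differed by 4.07 (SE 0.32). WRKY70 (BnaA07g16850D) and CNX1 (BnaA06g21300D) differed the other way, by -2.85 (SE 0.71) and -2.96 (SE 0.45). Calls were lost for CNX1, the thaumatin-like gene and VSP2 in a fit to only the groups compared and for CNX1, VSP2 and WRKY70 with voom weights. Further calls were lost for CNX1 and the thaumatin-like gene with the Westar mocks of 3 and 11 dpi as control. Of the 9 lists called by the preset test none held with an estimated correlation. In the jasmonate list 14 of 48 changed more upward in DF78 and 1 in Westar (22 and 2 adjusted over the list alone), with adjusted p = 0.12 with an estimated correlation, and in the photosynthesis list 2 of 162 changed more upward in DF78 and 76 in Westar (5 and 100 adjusted over the list alone), with adjusted p = 0.32. In the salicylic acid list 4 of 63 changed more upward in DF78 and 10 in Westar (5 and 18 adjusted over the list alone), with adjusted p = 0.55 with an estimated correlation. The list's median difference turned from -0.44 to 0.48 with voom weights, while the median over all genes moved from -0.07 to 0.42. Differences are relative to these medians. GRP3 (BnaA09g54870D) and chitinase BnaA10g05680D, high in the Westar mocks of 7 dpi, differed by 6.32 (SE 0.32) and 6.31 (SE 0.36), and with the Westar mocks of 3 and 11 dpi as control by -0.41 and -1.07. Of 55809 simulated unchanged genes 424 were called here, and voom weights called none of them. On the real data voom weights called 337 genes, 254 with the higher change in DF78 and 83 in Westar. The balance of directions thus turned, but that fit also raises genes near 0 in the shallow Westar libraries, apart from its weights. In 3174 of the 6131 genes (51.8%) the mocks differed more between the genotypes than the infected groups. The count was 10173 without Westar mock replicate 2, 10835 and 3856 without DF78 infected replicates 2 and 3, and 2738 and 3256 without DF78 mock replicates 1 and 2.

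At 11 dpi infected DF78 had its highest count of changed genes, 7640 of the 58564 genes tested, 4567 up and 3073 down. PR1 rose from 9.67 ± 1.33 to 1363 ± 91.1 FPKM (log2 change 7.00, SE 0.53, adjusted p = 3.3e-10). A basic PR1-type gene (BnaA03g38630D, chromosome A03, 19202989 to 19203618) rose from 8.62 ± 1.35 to 1562 ± 87.8 FPKM (log2 change 7.35, SE 0.97, adjusted p = 3.6e-06). PR4 (BnaC03g33890D, chromosome C03, 20607243 to 20608267) rose from 0.23 ± 0.0283 to 129 ± 3.36 FPKM (log2 change 6.73, SE 0.31, adjusted p = 2.8e-14). The thaumatin-like gene BnaC05g14950D rose by 8.11 (SE 0.76), a Kunitz trypsin inhibitor (BnaA07g22750D) by 7.11 (SE 0.74) and the senescence protease SAG12 (BnaA02g24130D) from 1.31 ± 0.148 to 60.8 ± 4.74 FPKM. LTP1 (BnaC04g06760D), a lipid transfer protein, fell from 48.8 ± 2.55 to 1.84 ± 0.675 FPKM. After quantile normalization 48.6% of the called genes were up, against 59.8% as deposited.

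Of the salicylic acid genes 41 of 63 rose and 3 fell (43 and 5 adjusted over the list alone, adjusted p = 0.0055 with an estimated correlation), with ALD1 up from 0.075 ± 0.00707 to 86.4 ± 5.03 FPKM. In the jasmonate list 25 of 48 rose and 3 fell (30 and 3 adjusted over the list alone, adjusted p = 0.0089 with an estimated correlation), with the repressor gene JAZ10 (BnaC09g43860D) and LOX2 copy BnaA07g24880D up by 3.48 (SE 0.32) and 3.31 (SE 0.23). Camalexin and indole glucosinolate genes changed in the same direction, as 36 of 53 rose and 3 fell (36 and 4 adjusted over the list alone, adjusted p = 0.0069 with an estimated correlation), and CYP79B2 rose by 3.12 (SE 0.45). Among chitinases, glucanases and defensins 13 of 28 rose (16 adjusted over the list alone, adjusted p = 0.0026 with an estimated correlation). Among detoxification genes 22 of 53 rose (24 up and 1 down adjusted over the list alone, adjusted p = 0.0015 with an estimated correlation). Among ethylene genes 18 of 50 rose (21 up and 1 down adjusted over the list alone, adjusted p = 0.020 with an estimated correlation). Among pattern receptor and early signalling genes 26 of 77 rose (33 up and 2 down adjusted over the list alone, adjusted p = 0.020 with an estimated correlation). In the senescence list 7 of 29 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.038 with an estimated correlation), SAG13 by 4.70 (SE 0.33). Within the phenylpropanoid list 4 of 59 rose and 12 fell (6 and 18 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.15). Among endoplasmic reticulum folding genes 12 of 25 rose (18 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.10). For the aliphatic glucosinolate list 4 of 25 rose and 9 fell (4 and 11 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.12). PAL1 fell, with a log2 change of -1.83 (SE 0.37). Without mock replicate 1 the count was 4064 and without mock replicate 2 it was 4115.

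Infected Westar at 11 dpi had higher senescence and salicylic acid genes and lower photosynthesis genes than its mock. The thaumatin-like gene BnaC05g14950D rose from 0.755 ± 0.0636 to 1239 ± 45.6 FPKM (log2 change 9.46, SE 0.76, adjusted p = 1.0e-10). GLIP3 rose from 0.915 ± 0.0495 to 988 ± 21.3 FPKM (log2 change 9.01, SE 0.53, adjusted p = 2.9e-13) and PR1 from 57.4 ± 7.47 to 2059 ± 33.2 FPKM (log2 change 5.15, SE 0.53, adjusted p = 1.0e-08). VSP2 fell from 2959.8 ± 29.7 to 1.37 ± 1.18 FPKM (log2 change -10.39, SE 0.60, adjusted p = 2.2e-13), as did a knottin-type peptide gene (BnaC04g49050D) and epithiospecifier protein (BnaA06g01390D), with log2 changes of -9.73 (SE 0.60) and -7.93 (SE 0.70). SAG12 rose from 0.020 ± 0.0283 to 49.8 ± 4.07 FPKM and NAP by 6.20 (SE 0.45), and PR4 was listed at 0 in both mocks and averaged 287 FPKM in infected tissue. In all 28011 of the 58564 genes tested changed, 14006 up and 14005 down.

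In the photosynthesis list 1 of 162 rose and 146 fell (1 and 146 adjusted over the list alone, adjusted p = 0.022 with an estimated correlation), with LHCB1.3 (BnaC07g09400D) down from 689.6 ± 71.8 to 20.8 ± 1.67 FPKM and RBCS1B (BnaCnng55860D) changed by -4.83 (SE 0.40). In the senescence list 23 of 29 rose and 6 fell (23 and 6 adjusted over the list alone, adjusted p = 0.0051 with an estimated correlation), with SAG21 (BnaA03g26220D) and SAG13 up by 7.46 (SE 0.46) and 6.94 (SE 0.33). Of the pattern receptor and early signalling genes 58 of 77 rose and 1 fell (60 and 1 adjusted over the list alone, adjusted p = 0.0097 with an estimated correlation). The transcription factor gene WRKY33 of that list rose from 0.875 ± 0.2899 to 65.2 ± 2.295 FPKM. Among salicylic acid genes 49 of 63 rose and 4 fell (49 and 4 adjusted over the list alone, adjusted p = 0.022 with an estimated correlation). Among ethylene genes 34 of 50 rose and 2 fell (34 and 2 adjusted over the list alone, adjusted p = 0.040 with an estimated correlation). Among detoxification genes 34 of 53 rose and 4 fell (34 and 4 adjusted over the list alone, adjusted p = 0.0012 with an estimated correlation), with GSTU10 (BnaCnng35440D) up from 0.88 ± 0.976 to 278 ± 1.89 FPKM. Among the chitinase, glucanase and defensin genes 17 of 28 rose and 5 fell (18 and 5 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.16). Within the aliphatic glucosinolate list 2 of 25 rose and 14 fell (2 and 14 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.31). Among camalexin and indole glucosinolate genes 24 of 53 rose and 9 fell (24 and 9 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.42). For the endoplasmic reticulum folding list 16 of 25 rose (19 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.26). CHIB (BnaC03g37570D) and CYP83A1 (BnaC04g29320D) fell, with log2 changes of -6.05 (SE 0.78) and -5.93 (SE 0.53), while C4H (BnaA04g17560D) of phenylpropanoid synthesis rose by 5.06 (SE 0.25). In the jasmonate list 18 of 48 rose and 11 fell (18 and 12 adjusted over the list alone), and the list was not called. No call was made for CHIB and epithiospecifier protein with the 0 dpi libraries as control.

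The responses at 11 dpi differed between the genotypes in 14699 of the 58564 genes tested, 7678 with the higher change in DF78 and 7021 in Westar. VSP2 stood at 1.18 ± 0.316 FPKM in infected and 3.32 ± 0.184 FPKM in mock DF78 against 1.37 ± 1.18 and 2959.8 ± 29.7 FPKM in Westar (difference 9.40, SE 0.85, adjusted p = 8.7e-09). LHCB1.3 (BnaC07g09400D) stood at 34.8 ± 6.86 and 20.8 ± 2.47 FPKM in DF78 against 20.8 ± 1.67 and 689.6 ± 71.8 FPKM in Westar (difference 5.69, SE 0.39, adjusted p = 6.6e-11). GSTU24 (BnaC08g37940D) and NAP differed by -6.67 (SE 0.49) and -6.44 (SE 0.64). In the photosynthesis list 139 of 162 changed more upward in DF78 (142 adjusted over the list alone). In the senescence list 4 of 29 changed more upward in DF78 and 20 in Westar (5 and 21 adjusted over the list alone). In the detoxification list 3 of 53 changed more upward in DF78 and 23 in Westar (3 and 25 adjusted over the list alone), each with adjusted p = 0.0080 with an estimated correlation. The mocks differed with them: between mock groups of 11 dpi 19508 genes differed by genotype and between infected groups 9305, and in 11587 of the 14699 genes (78.8%) the difference between mocks was the larger. For pattern receptors and early signalling 31 of 77 changed more upward in Westar (33 adjusted over the list alone). That call was lost with adjusted p = 0.065 with an estimated correlation. For salicylic acid 3 of 63 changed more upward in DF78 and 15 in Westar (3 and 15 adjusted over the list alone). For jasmonate 14 of 48 changed more upward in DF78 and 5 in Westar (15 and 5 adjusted over the list alone), both with adjusted p = 0.49 with an estimated correlation.

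**Figure D2:**
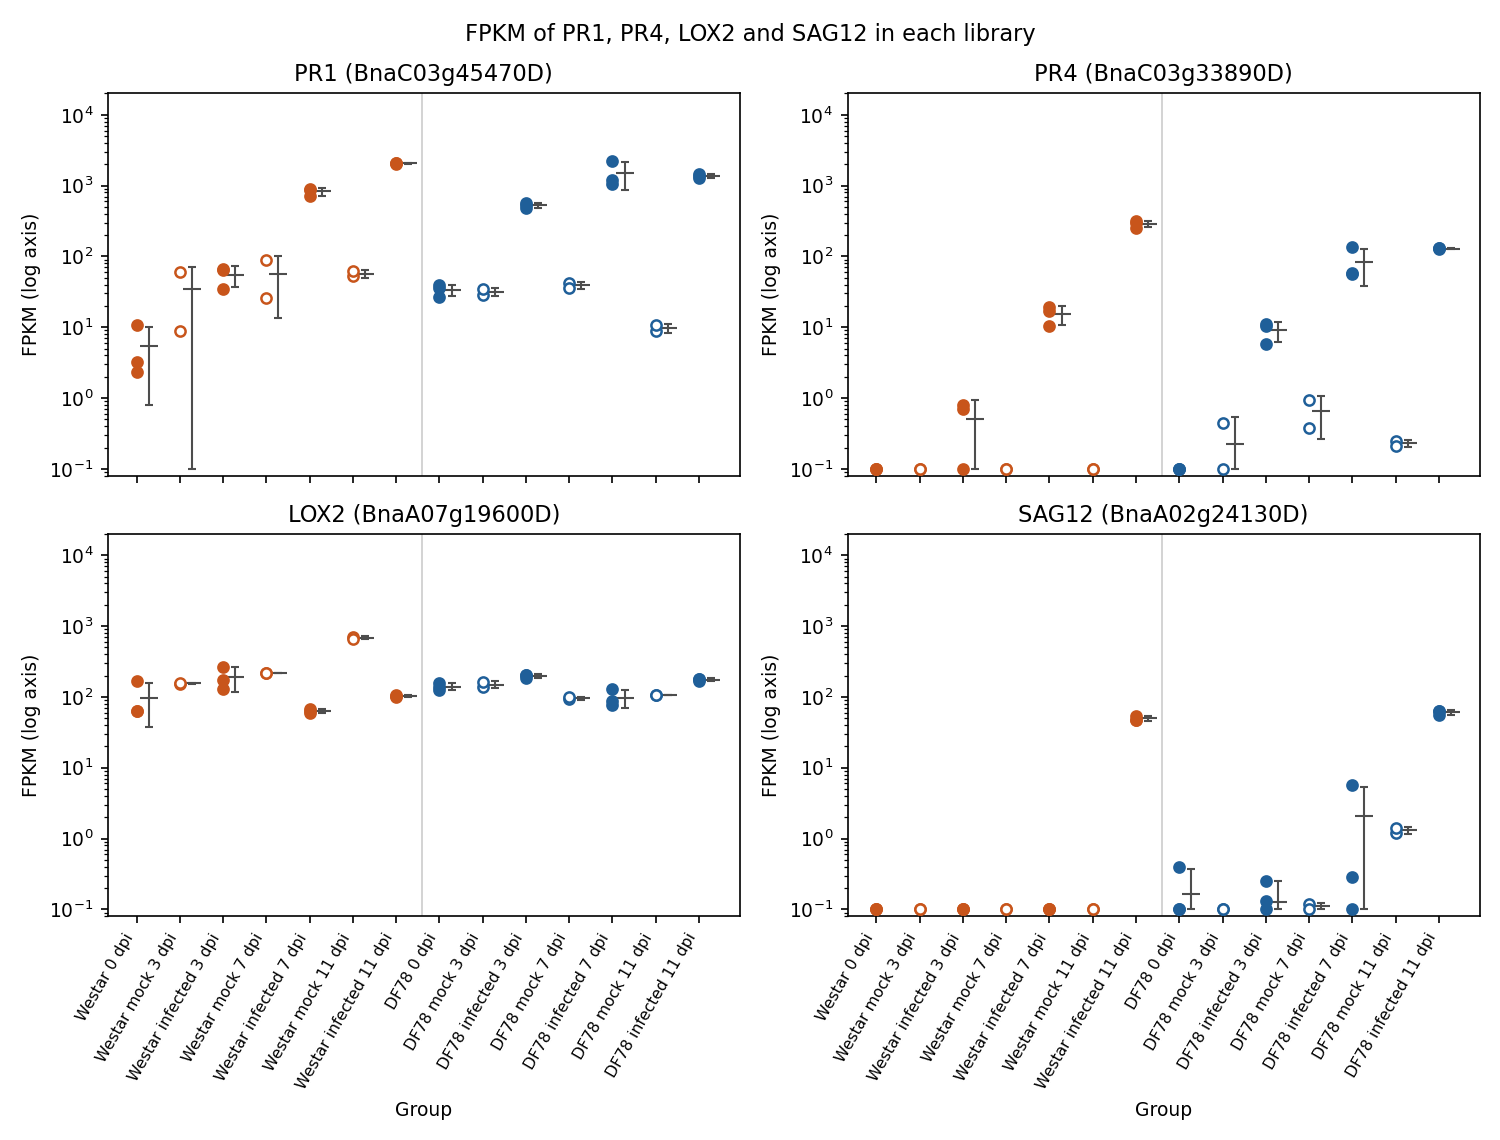
FPKM per library (y axis, log scale) of PR1 (BnaC03g45470D), PR4 (BnaC03g33890D), LOX2 (BnaA07g19600D) and SAG12 (BnaA02g24130D) by group (x axis), with points for libraries (open for mock, values under 0.1 FPKM drawn at 0.1) and a dash with bars for the mean ± 1 SD, the bar ending at 0.1 FPKM and no mean drawn at or below that value. PR1 averaged 531 FPKM in infected DF78 against 55.4 FPKM in infected Westar at 3 dpi, and SAG12 60.8 and 49.8 FPKM at 11 dpi.

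Markers of other cell types and reference genes were tested as lists of their own. In the vascular list 3 of 22 fell (3 adjusted over the list alone) in DF78 at 11 dpi (adjusted p = 0.038 with an estimated correlation), all of them xylem peptidase genes (XCP1 and XCP2), and in infected Westar at 7 and 11 dpi 5 of 22 rose and 3 fell (5 and 3 adjusted over the list alone) and 2 of 22 rose and 7 fell (1 and 7 adjusted over the list alone), with no call of the list. With voom weights 0 vascular genes rose and 0 fell in Westar at 7 dpi. In infected DF78 at 7 dpi no vascular member of 22 passed over all genes, against 0 up and 2 down at an unadjusted p under 0.05 and 0 up and 0 down adjusted over the list alone, and that call was lost with adjusted p = 0.15 with an estimated correlation and also after quantile normalization. Of the guard cell markers 4 of 9 fell (4 adjusted over the list alone) in Westar at 7 dpi, with adjusted p = 0.18 with an estimated correlation, MYB60 (BnaCnng06440D) from 14.5 ± 2.29 to 4.26 ± 1.27 FPKM, a call lost with the Westar mocks of 3 and 11 dpi as control (change of -0.25), and voom weights gave 0 up and 1 down in that list. Both seed storage genes tested encode oleosin OLEO1, and 2 of 2 rose (2 adjusted over the list alone) in infected Westar at 7 dpi without a call of the list, BnaC08g11970D from 2.02 ± 0.658 to 18.7 ± 1.399 FPKM. With voom weights neither was called (0 of 2), although the median change was 2.05 in both fits, and the mock level lies below the 3.63 and 5.81 FPKM that 3 fragments on a gene of 1 kb give in these mocks. In the housekeeping list 7 of 33 rose and 7 fell (8 and 8 adjusted over the list alone) at 7 dpi and 10 of 33 rose and 5 fell (10 and 5 adjusted over the list alone) at 11 dpi in infected Westar, again without a call, and with voom weights 1 rose and 2 fell at 7 dpi. The actin gene ACT7 (BnaA02g00190D) stood at 61.9 ± 0.511 against 57.8 ± 2.47 FPKM in Westar (log2 change 0.10, SE 0.15, adjusted p = 0.65) and 91.5 ± 3.55 against 80.9 ± 2.55 FPKM in DF78 (log2 change 0.17, SE 0.15, adjusted p = 0.56) at 11 dpi. The polyubiquitin gene UBQ10 (CUFF.17731.3), another reference gene, rose from 85.4 ± 4.07 to 279.6 ± 4.12 FPKM in Westar (log2 change 1.70, SE 0.22, adjusted p = 3.1e-07) and from 143 ± 9.2 to 239 ± 7.98 FPKM in DF78 (log2 change 0.74, SE 0.22, adjusted p = 0.021). In DF78 that call was lost without DF78 infected 11 dpi replicate 2 (0.063), DF78 mock 11 dpi replicate 1 (0.18) or DF78 mock 11 dpi replicate 2 (0.088), and when an absolute log2 change of at least 1 was asked for.

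Across genes, the responses of the genotypes correlated with Pearson r = 0.014 and Spearman rho = -0.0065 at 3 dpi, r = 0.474 and rho = 0.433 at 7 dpi, and r = 0.523 and rho = 0.442 at 11 dpi, where genes are not independent replicates and the genotypes share no library. At 3 dpi 4 genes rose in both (0.3 expected for independent lists), but with voom weights 0 did (0.2 expected) and r was -0.140, where limma called 17 genes up in Westar and 680 in DF78. At 7 dpi 1804 rose in both (514 expected) and 575 fell in both (202 expected), and at 11 dpi 3698 rose (1092 expected) and 1857 fell (735 expected). Under voom weights 931 rose in both (97.3 expected) and 721 fell in both (165 expected) at 7 dpi, and 5267 rose (1812 expected) and 3350 fell (1500 expected) at 11 dpi. Without infected DF78 replicate 2 the correlation at 7 dpi was 0.265. The authors' deposited table lists 1825, 5370 and 9717 genes for DF78 and 583, 5959 and 13534 for Westar at 3, 7 and 11 dpi. Both subgenomes contributed, with 45.1% to 49.6% of the genes called in each comparison on A chromosomes against 46.8% of the genes tested. Among the authors' called genes the share on A was 52.7%, 48.25% and 56.9% for DF78 at 3, 7 and 11 dpi. For Westar on those days it was 56.3%, 48.7% and 49.7%. Why these shares differ from those found here was not tested.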

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

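Of the tests reported here, those on another set of Westar mocks, on DF78 material in the Westar mocks, on the second set of genotype markers, on a fungal response in the DF78 mocks and on other splits of the libraries were chosen after the result was seen, as were the fits with voom weights. The results listed first were singled out because the test of the difference between the genotypes' responses passed. Libraries named in brackets carry the adjusted p without that library.

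At 3 dpi 103 genes differed. The median difference (DF78 minus Westar) was 0.64 in the salicylic acid list, 0.63 for aliphatic glucosinolates, 0.26 for phenylpropanoids, 0.55 for sulfur and 0.51 for detoxification. SAG13 (BnaA04g17120D) differed by 2.99 (SE 0.47), adjusted p = 0.0024. ALD1 (BnaA03g38440D) differed by 2.68 (SE 0.57), adjusted p = 0.045, and lost its call without Westar infected 3 dpi replicate 1 (0.074), Westar infected 3 dpi replicate 2 (0.079), Westar mock 3 dpi replicate 2 (0.14), DF78 infected 3 dpi replicate 1 (0.076), DF78 infected 3 dpi replicate 2 (0.062), DF78 infected 3 dpi replicate 3 (0.14), DF78 mock 3 dpi replicate 1 (0.19) or DF78 mock 3 dpi replicate 2 (0.27). PR4 (BnaC03g33890D) differed by 2.47 (SE 0.44), adjusted p = 0.0084, and lost its call without DF78 mock 3 dpi replicate 2 (0.15). Calls were lost for PR4 and SAG13 in a fit to only the groups compared and for ALD1 and PR4 with voom weights and with a pseudocount of 0.1. Further calls were lost for ALD1 with no filter and with the replicate block. Without Westar mock replicate 1 the count was 1862 (738 with the higher change in DF78 and 1124 in Westar) and without DF78 mock replicate 2 it was 34, with 157 without Westar infected replicate 3 and 68 without DF78 infected replicate 3.

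At 7 dpi 6131 genes differed, and in 3174 of them (51.8%) the mocks differed more between genotypes than the infected groups. LOX2 (BnaA07g19600D) differed by 1.77 (SE 0.41), adjusted p = 0.0068. AOS (BnaA02g23180D) differed by 2.00 (SE 0.49), adjusted p = 0.0104, and lost its call without DF78 mock 7 dpi replicate 1 (0.066). CYP79B2 (BnaC07g51280D) differed by 2.39 (SE 0.63), adjusted p = 0.017, and lost its call without DF78 mock 7 dpi replicate 1 (0.063) or DF78 mock 7 dpi replicate 2 (0.054). PR4 (BnaC03g33890D) differed by 1.57 (SE 0.44), adjusted p = 0.023, and lost its call without Westar infected 7 dpi replicate 3 (0.053) or DF78 mock 7 dpi replicate 1 (0.13). FMO1 (BnaC08g18680D), an enzyme of systemic resistance, differed by -1.98 (SE 0.44), adjusted p = 0.0055. MYB51 (BnaA08g22580D), a regulator of indole glucosinolates, differed by -2.37 (SE 0.46), adjusted p = 0.0017. Calls were lost for FMO1, LOX2, MYB51 and PR4 in a fit to only the groups compared and for CYP79B2, LOX2, MYB51 and PR4 with voom weights. Further calls were lost for PR4 with array weights and for AOS, CYP79B2 and MYB51 with the Westar mocks of 3 and 11 dpi as control. PR4, FMO1 and MYB51 were listed at 0 in both Westar mocks of 7 dpi. The difference turned to -0.47 for PR4 with a pseudocount of 0.1 and to 1.55 for FMO1 with voom weights. The count was 10173 without Westar mock replicate 2, 10835 and 3856 without DF78 infected replicates 2 and 3, and 2738 and 3256 without DF78 mock replicates 1 and 2.

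At 11 dpi 14699 genes differed, and in 11587 of them (78.8%) the mocks differed more between genotypes than the infected groups. PR2 (BnaC04g24330D) stood at 654 ± 34.7 FPKM in infected and 20.2 ± 1.35 FPKM in mock DF78 against 1502 ± 98.3 and 189 ± 9.55 FPKM in Westar. LOX2 (BnaA07g19600D) stood at 175 ± 8.57 and 107.5 ± 0.0141 FPKM in DF78 against 103 ± 1.98 and 682 ± 32.8 FPKM in Westar. The median difference was 2.62 in the photosynthesis list, -1.70 in the senescence list and -1.12 in the detoxification list. LOX2 (BnaA07g19600D) differed by 3.41 (SE 0.41), adjusted p = 9.0e-07. AOS (BnaA02g23180D) differed by 3.36 (SE 0.49), adjusted p = 1.4e-05. CYP79B2 (BnaC07g51280D) differed by 2.65 (SE 0.63), adjusted p = 0.0028. WRKY33 (BnaC03g21360D) differed by -2.86 (SE 0.56), adjusted p = 0.00048. SAG13 (BnaA04g17120D) differed by -2.25 (SE 0.47), adjusted p = 0.00079. PR2 (BnaC04g24330D) differed by 1.97 (SE 0.65), adjusted p = 0.027, and lost its call without Westar mock 11 dpi replicate 1 (0.066), Westar mock 11 dpi replicate 2 (0.079), DF78 mock 11 dpi replicate 1 (0.084) or DF78 mock 11 dpi replicate 2 (0.063). FMO1 (BnaC08g18680D) differed by -1.34 (SE 0.44), adjusted p = 0.027, and lost its call without Westar mock 11 dpi replicate 1 (0.075), Westar mock 11 dpi replicate 2 (0.072), DF78 mock 11 dpi replicate 1 (0.074) or DF78 mock 11 dpi replicate 2 (0.074). PR4 (BnaC03g33890D), listed at 0 in both Westar mocks, differed by -1.44 (SE 0.44), adjusted p = 0.017, and lost its call without Westar mock 11 dpi replicate 1 (0.053) or DF78 mock 11 dpi replicate 1 (0.056). The co-receptor BAK1 (BnaC01g04780D) differed by -1.16 (SE 0.34), adjusted p = 0.015, and lost its call without Westar mock 11 dpi replicate 2 (0.068) or DF78 mock 11 dpi replicate 2 (0.071). The chitin receptor CERK1 (BnaC05g30720D) differed by -1.16 (SE 0.35), adjusted p = 0.015, and lost its call without DF78 mock 11 dpi replicate 1 (0.057). UBQ10 (CUFF.17731.3), a reference gene, differed by -0.96 (SE 0.30), adjusted p = 0.022, and lost its call without Westar mock 11 dpi replicate 1 (0.051), Westar mock 11 dpi replicate 2 (0.075) or DF78 mock 11 dpi replicate 2 (0.083). Calls were lost for FMO1 and PR4 with voom weights and for FMO1 with a pseudocount of 0.1. Further calls were lost for UBQ10 when an absolute log2 change of at least 1 was asked for.

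In Westar at 7 dpi 22014 genes were called, in the comparison that held the 3 libraries under 1 M fragments. Low depth may add calls: with the matching DF78 libraries thinned to the same totals, the DF78 comparison called a median of 8417 genes (at least 8186 in each of 10 draws) against 3654 at full depth over the 58185 genes with a known length (3677 over all genes tested). A difference of these mocks from other Westar mocks stays open: with the Westar mocks of 3 and 11 dpi as control 20191 genes were called (9102 up and 11089 down, 12430 shared), but mocks also differ by day (11553 genes between 0 and 11 dpi), so the shared genes replaced the total as criterion after it was seen, and the difference between genotypes fell from 6131 to 2442 genes (1196 shared). DF78 material in the Westar mocks could neither be shown nor excluded by single markers. Of 9 marker genes of DF78, 3 stood at 10.1% to 23% of their DF78 level. The other 6 were listed at 0, where at most 2.82 fragments were expected in any single marker. Over those 6 together 7.18 fragments were expected, above the floor of 3, which would have argued against such material at an even share. The criterion was changed to single markers after that value was seen, so the question was left undecided.

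Mock tissue of 11 dpi differed between the genotypes in 19508 genes, and its changes since 0 dpi correlated with r = -0.0060 between them. A wrong genotype label is argued against by 7 markers that part the genotypes in all other libraries, with 100% on the labelled side in the 4 mocks, whereas the first set of 26 markers, with 76.9% at the lowest, fell between its bounds. A response to the fungus in the DF78 mocks is argued against, as 12.7% of 283 early response genes lay above the midpoint between 0 dpi and infected tissue (median change 0.53 in mock and 4.25 in infected tissue). Ageing of DF78 cotyledons remains a candidate explanation, as the change from 7 to 11 dpi correlated across genes with that from 0 to 3 dpi at r = 0.329. In Westar r was 0.064, but it rests on mocks of 7 dpi with 0.34 and 0.563 M fragments. Noise at that depth lowers r, so the values cannot show that ageing differed between the genotypes. Differences in growth between the genotypes stay open and were not tested.

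For DF78 against Westar at 0 dpi, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split called 11642 genes and the highest of the others 1355, and 1 of the 10 splits, the real one, gave as many. The genetic difference of the genotypes is named by the design and was not tested apart from other differences.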

How the results depend on the processing

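The fits with voom weights, with array weights, without the shallow libraries and with the Westar mocks of 3 and 11 dpi were chosen after seeing the data. Counts of called genes stayed within 1.5 times of those reported under median-of-ratios rescaling, quantile normalization, the replicate block, and no trend with robust variances. Where a count moved further, the cause was not tested, except that a mean of at least 5 FPKM tests fewer genes. A pseudocount of 0.1 gave 60 for the difference at 3 dpi, no filter gave 157 for Westar 3 dpi, and asking for an absolute log2 change of at least 1 gave 6794 for 0 dpi. A mean of at least 5 FPKM gave 10841 for Westar 7 dpi, 13625 for Westar 11 dpi, 2346 for DF78 7 dpi, 4282 for DF78 11 dpi, 2983 for the difference at 7 dpi, 9106 for the difference at 11 dpi, 6767 for 0 dpi, 6795 for Westar mock 11 dpi and 10317 for DF78 mock 11 dpi. Only the groups compared gave 0 for Westar 3 dpi, 5865 for Westar 7 dpi, 958 for DF78 3 dpi, 202 for DF78 7 dpi, 18054 for DF78 11 dpi, 550 for the difference at 7 dpi, 26797 for the difference at 11 dpi, 5078 for 0 dpi and 5290 for Westar mock 11 dpi, where limma called no gene in Westar at 3 dpi although 5153 passed an unadjusted p under 0.05 in the fit to all groups and 64 were called with voom weights. The 0 dpi libraries as control gave 2267 for Westar 3 dpi, 9219 for DF78 3 dpi, 12748 for DF78 7 dpi and 27320 for DF78 11 dpi. Voom weights gave 5101 for Westar 7 dpi, 723 for DF78 3 dpi, 6267 for DF78 7 dpi, 11888 for DF78 11 dpi, 337 for the difference at 7 dpi and 17701 for Westar mock 11 dpi. Array weights gave 2 for Westar 3 dpi, 8705 for Westar 7 dpi, 4036 for DF78 3 dpi, 6723 for DF78 7 dpi, 23893 for DF78 11 dpi, 4016 for the difference at 7 dpi, 31070 for the difference at 11 dpi, 29675 for 0 dpi, 29717 for Westar mock 11 dpi and 31269 for DF78 mock 11 dpi. Without the shallow libraries 286 for Westar 3 dpi and 246 for the difference at 3 dpi were called, and with the Westar mocks of 3 and 11 dpi 2442 for the difference at 7 dpi. Of 114 list calls 38 held with an estimated correlation and 113 with the replicate block.

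Leaving out each library in turn gave 69 to 2878 for Westar 3 dpi, 20105 to 21354 for Westar 7 dpi, 21734 to 25936 for Westar 11 dpi, 123 to 287 for DF78 3 dpi, 1477 to 4378 for DF78 7 dpi, 4064 to 6046 for DF78 11 dpi, 34 to 1862 for the difference at 3 dpi, 2738 to 10835 for the difference at 7 dpi, 10387 to 13236 for the difference at 11 dpi, 5958 to 15665 for 0 dpi, 4973 to 14730 for Westar mock 11 dpi and 11234 to 15899 for DF78 mock 11 dpi. The correlation of responses was -0.140 at 3 dpi and 0.558 at 11 dpi with voom weights, and 0.795 at 11 dpi with the 0 dpi libraries as control. Leaving out libraries it ran from -0.0739 to 0.111 at 3 dpi, 0.265 to 0.530 at 7 dpi and 0.499 to 0.523 at 11 dpi.

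Of 2686 alternative values of 143 named gene results 2570 stayed on their side of the threshold with their direction, 7 gained a call and 5 turned. The others lost a call, which stands beside the result. Calls were gained for PR1 in Westar 3 dpi and ACT7 in DF78 11 dpi with the 0 dpi libraries, for ACT7 in DF78 11 dpi and PR1 in the difference at 3 dpi with array weights and for ACT7 in Westar 11 dpi after quantile normalization.

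Directions of named genes turned in these settings, and the cause was not tested. With 0 dpi libraries as control the log2 difference was 0.12 for BnaAnng41910D in Westar 3 dpi. With Westar mocks of 3 and 11 dpi as control the log2 difference was -0.41 for BnaA09g54870D in the difference at 7 dpi and -1.07 for BnaA10g05680D in the difference at 7 dpi. With pseudocount 0.1 the log2 difference was -0.47 for BnaC03g33890D in the difference at 7 dpi. With voom weights on recovered fragments the log2 difference was 1.55 for BnaC08g18680D in the difference at 7 dpi. In that fit the median difference over all genes also moved, from -0.07 to 0.42, and its scale as well as its weights differ from the main fit.

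Replicate numbers did not pair the libraries, with correlations of same-numbered deviations from -0.118 to 0.095, and not every library correlated best with its own number. The replicate block gave counts between 62 for Westar 3 dpi and 27672 for Westar 11 dpi. The planned rescaling without fungal genes and the fungal share were not run, because the table used here holds no named fungal genes. Depth limits Westar at 7 dpi most, where 3 fragments of a 1 kb gene equal up to 5.81 FPKM.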

Other observations

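The families were tested after the lists, over every annotated family of at least 20 genes, and these results were chosen for display after they were seen. In infected DF78 at 7 dpi, O-methyltransferase genes moved up, where 13 of 40 rose (adjusted p = 0.043 with an estimated correlation), and so did genes of the SPFH and prohibitin type, where 8 of 31 rose (adjusted p = 0.043 with an estimated correlation). Among S-locus lectin kinases 12 of 52 rose (adjusted p = 0.044 with an estimated correlation), and of the genes annotated like the cysteine-rich receptor kinase CRK11, 8 of 20 rose (adjusted p = 0.043 with an estimated correlation). At 11 dpi 17 of 31 rose and 1 fell (adjusted p = 0.014 with an estimated correlation) of the SPFH genes and 15 of 44 rose and 1 fell (adjusted p = 0.033 with an estimated correlation) of the auxin-responsive GH3 genes, which conjugate hormones to amino acids.

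In infected Westar at 11 dpi 40 of 65 rose and 3 fell (adjusted p = 0.030 with an estimated correlation) among VQ motif genes, which encode partners of WRKY factors, and 13 of 20 rose (adjusted p = 0.030 with an estimated correlation) among the CRK11-type kinases. Fibrillins of the plastid fell, as 16 of 23 fell (adjusted p = 0.030 with an estimated correlation), and among GDSL lipases 9 of 93 rose and 46 fell (adjusted p = 0.040 with an estimated correlation). In mock Westar between 0 and 11 dpi 19 of 23 rose (adjusted p = 0.0037 with an estimated correlation) among mitochondrial glycoproteins and 9 of 24 rose (adjusted p = 0.018 with an estimated correlation) among Kunitz inhibitors. In mock DF78 23 of 47 fell (adjusted p = 0.0017 with an estimated correlation) among Pollen Ole e 1 genes and 3 of 112 rose and 44 fell (adjusted p = 0.015 with an estimated correlation) among pectin lyase-like genes.

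Some replicates differed far more than others of their group. The chi-square per degree of freedom between fragment counts was 39.7 and 29.8 for pairs with replicate 2 of infected DF78 at 7 dpi and 2.44 for the remaining pair. For Westar at 0 dpi it was 44.9 and 40.6 for pairs with replicate 1 and 2.97 for the other pair, and for the Westar mocks of 3 dpi it was 17.7. Infected libraries of 11 dpi lay near sampling noise, from 1.24 to 1.67 in Westar and from 1.39 to 2.01 in DF78. In infected Westar at 3 dpi it was 21.0 between replicates 2 and 3 and 6.99 and 7.58 for the pairs with replicate 1. This value grows with depth, and replicate 1 held 2.48 M fragments against 14.1 and 9.53 M. By Pearson r of log2 values replicates 2 and 3 were the most alike, at 0.954 against 0.946 and 0.944.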
